A study of Oryza sativa with 3 samples.

How the data were processed

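RNA from rice roots (Oryza sativa, cultivar TN67) was measured on 3 two-channel Agilent arrays. Each array carried 1 biological replicate, with RNA of vanadate-treated roots labelled with Cy5 (red) and RNA of water-treated roots labelled with Cy3 (green), per the labels' protocols. RNA of the 1 h and 3 h time points was pooled by fixed volume before labelling, so the times cannot be separated. The labels describe 0 arrays with exchanged dyes, so a dye effect would repeat on every array and cannot be told apart from a treatment effect.

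The scanner files hold spot intensity values written by Agilent Feature Extraction 10.7.1.1, per the file headers. The median signal and median local background intensity of each channel are uncorrected, while the processed signal intensity is background-subtracted and dye-normalized by that software, per the file headers. The log10 ratio column of the scanner files is computed by the same software from the processed signals, red over green, per the file headers, and was not tested. The authors' deposited value table holds log2 ratios. Of its 42474 probes, 42415 matched a gene probe of the scanner files, and at least 99.9% of the matched values per array lay within 0.001 of log2 of processed red over processed green signal averaged over spots. The deposited log2 ratios therefore run as vanadate over water and are not centred, with medians of -0.19, -0.21 and -0.05 on the arrays of replicates 1, 2 and 3.

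In the analysis made here, background was corrected with normexp at an offset of 50, and log ratios were normalized within each array by loess, in limma 3.58.1 under R 4.3.3. The design fixed before the data were examined named the mean spot signal. The scanner files used here give the median signal and not the mean signal, so the median signal was used in its place. Control spots had weight 0 in loess and were then left out, as were spots with a non-uniformity or population outlier flag in either channel. Spots of a probe were averaged. A probe was tested when it had a value on all 3 arrays and was well above background in at least 1 channel on at least 2 arrays, which kept 31108 of 42418 gene probes. The mean log2 ratio of the 3 arrays was tested against 0 with limma's lmFit and eBayes, with Benjamini-Hochberg adjustment over all tested probes and a threshold of 0.05. A gene is a locus ID from the probe name, represented by its tested probe of highest mean intensity, which gave 22113 tested genes of 29860. SE values are limma's moderated standard errors, and SD values are the spread of the 3 log2 ratios.

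Where a probe was not well above background in one channel on any array, only a bound on its fold is given. The bound sets the mean of the brighter channel against the mean, over arrays, of the higher of the dim probe's own level and the lowest level among probes well above background, on log2 channel levels after loess and Aquantile. Where the dim probe's own level was the higher on every array, the bound equals the fold. These bounds leave out the error between arrays and are open to dye bias.

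The arrays of replicates 1 and 2 shared a slide and a scan day, and the array of replicate 3 was on another slide scanned on another day, per the file headers. Gene spots well above background made up 69.9%, 69.0% and 75.3% in the water channel and 74.2%, 73.7% and 76.1% in the vanadate channel of replicates 1, 2 and 3. No spot was saturated. Outlier flags removed 172, 129 and 958 of 43144 gene spots. The median signal of negative control spots in the water channel was 160, 154.5 and 89 against a median local background of 62.5, 62 and 37, and in the vanadate channel 67, 68 and 62 against 63.5, 65 and 59. The number of arrays limits the precision of every value.

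Of 37 gene lists fixed before the data were examined, 32 were defined only by words in gene descriptions. The files used here pair no locus ID with a description. The reference table of assembly ASM3414082v1 held only 1 locus ID of this form and matched 0 of the 29860 gene IDs of the array. These 32 lists therefore had no members. The other 5 lists were fixed as words plus locus IDs from background knowledge. Their words also matched 0 genes, so each list held only its loci, between 2 and 9 of them. Their membership was not checked against an annotation. Members were counted with the adjustment over all probes and over the list alone. Lists with at least 5 tested genes were tested with camera at a preset correlation of 0.01 and at an estimated correlation, and with fry, with Benjamini-Hochberg adjustment over the 2 lists. Each such list's median was also set against 10000 random lists matched on mean intensity, with each member drawn independently.

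The rule for named genes, fixed before the data were examined, took the 6 genes with the largest rise and the 6 with the largest fall among called genes with a described function, up to 3 called genes of each list of pathways (the top 2 of each direction where both had at least 2), 1 gene of each list of cell types, and 4 reference genes. Its first part selected no gene in the absence of descriptions, so the 2 genes with the largest rise and the 2 with the largest fall are given by locus ID. MicroRNA loci are named by their probe names and were chosen after their values were seen, as the 3 with the largest fall and the 1 with the largest rise in the mean of both flanking probes.

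The test was checked on simulated log ratios for the 31108 probes with the observed spread of each probe. With 200 probes changed, 0% were recovered at a 1.41-fold change, 52% at 2-fold and 96.5% at 4-fold. False calls numbered 0, 3 and 6 in these runs, and 0 in a run with no changed probe. In the data 15349 of 31108 probes were called, so a larger p passes the adjustment there and these rates do not carry over. The simulated noise was independent between probes and held no dye effect. Alternatives tried were the scanner software's processed signals, no background subtraction, median centring, no filter and a strict filter on dim probes, retained outlier spots, an intensity trend in the spread, the authors' value table, channels as separate samples, the mean over a gene's probes, and each replicate left out. Alternatives added after the data were seen were a background from negative control spots, processed signals with the strict filter, slide as a fixed block, and counts over single microRNA probes.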

Results

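Transcript levels were measured in roots of 6-day-old rice seedlings exposed to 1 mM vanadate or to water. Vanadate is an oxyanion of vanadium that resembles phosphate and inhibits P-type ATPases. The design comprised 3 biological replicates, each a pool of RNA from 1 h and 3 h of exposure and each hybridised as vanadate against water on 1 array. Log2 ratios correlated across probes between arrays, with Pearson's r of 0.93 for replicates 1 and 2, 0.89 for replicates 1 and 3 and 0.92 for replicates 2 and 3. Probes are not independent replicates. All log2 ratios are vanadate over water, with n = 3 arrays.

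The comparison of vanadate with water asked which root transcripts changed under vanadium stress. Of the 22113 tested genes, 6439 were called higher in vanadate and 4575 lower (limma, adjusted p under 0.05). A dye effect that repeats on all 3 arrays would be called in the same way, since the dyes were not exchanged. Of 52 control probes well above background in neither channel on any array, 4 were called higher and 4 lower, at -0.16 to 0.18. The control probes were fitted and adjusted apart from the gene probes, so these calls give no error rate for the gene test. POsControl0009 was called at 0.18 ± 0.03 (SE), while the gene Os03g0177900 at 0.18 ± 0.08 (SE) was not. Large changes were mostly rises: 1872 genes rose at least 2-fold and 341 fell at least 2-fold, and at least 8-fold changes comprised 232 rises and 0 falls. The latter were 672 and 2 with the processed signals and 597 and 7 in the authors' value table. At an unadjusted p under 0.05, 7176 genes were higher and 5477 lower. The largest rise was that of Os04g0203600, with a log2 ratio of 7.68 ± 0.12 (SE, adjusted p = 2.32e-06), a 205-fold difference, and its water channel was well above background on 2 of the 3 arrays. Os08g0177400 followed with a log2 ratio of 7.16 ± 0.17 (SE, adjusted p = 2.40e-06), a 143-fold rise. With the processed signals these rises were 472-fold and 235-fold. Among the falls, Os07g0677300 was 5.19-fold lower under vanadate at a log2 ratio of -2.38 ± 0.11 (SE, adjusted p = 1.69e-05), and its second probe was also called lower. Os04g0515900 was 5.11-fold lower at a log2 ratio of -2.35 ± 0.15 (SE, adjusted p = 6.77e-05), and 8.32-fold lower in the authors' value table. The order of these 2 falls depends on the setting, since Os04g0515900 was the lower with the processed signals, at -2.91 against -2.42.

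In 500 genes the vanadate channel was well above background on all 3 arrays and the water channel on 0, and the reverse held for 54 genes. Negative control spots had a median signal of 160, 154.5 and 89 in the water channel and of 67, 68 and 62 in the vanadate channel of replicates 1, 2 and 3. For genes with several tested probes, 92.1% of the other 4562 probes of called genes pointed the same way as the representative probe, and 2.54% were called the opposite way. Rises made up 58.5% of all calls and 84.6% of calls of at least 2-fold. In the authors' value table, which is not centred, these shares were 42.2% and 68.5%, and the median log2 ratio of all tested genes was -0.11 against 0.02 here. With slide as a fixed block, 6897 genes rose and 5147 fell. In that fit the spread rests on replicates 1 and 2 alone, since the other slide held the 1 array of replicate 3. Within the slide of replicates 1 and 2 these numbers were 5909 and 3772, and the other slide allows no test. Without replicate 2, 2761 genes fell.

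The iron deficiency list covers the synthesis and transport of iron-chelating phytosiderophores and iron uptake. Of its 9 tested members, 7 fell under vanadate, 0 rose and 2 were not called. Adjusted over the list alone, 7 fell and 1 rose, Os03g0667500 at 0.25 ± 0.09 (SE). The largest fall was that of Os03g0307300, 3.46-fold lower at a log2 ratio of -1.79 ± 0.27 (SE, adjusted p = 0.00239 in limma). Its neighbour by locus number, Os03g0307200, was 2.63-fold lower at -1.39 ± 0.32 (SE, adjusted p = 0.0134 in limma). Os02g0650300 was 2.58-fold lower at -1.37 ± 0.10 (SE, adjusted p = 0.000137 in limma), a call lost with channels as separate samples (adjusted p = 0.163). The list's median log2 ratio was -0.66, below all of 10000 random lists matched on intensity, with medians of -1.16, -0.70 and -0.49 on replicates 1, 2 and 3. It was -1.36 with the processed signals and -1.52 in the authors' value table. The random lists drew each gene independently, while camera estimated a correlation of 0.53 between the members. Independent draws can therefore vary too little to judge this list. The list was lower than other genes in camera (adjusted p = 0.00741), with slide as a fixed block (adjusted p = 0.00279) and within the slide of replicates 1 and 2 (adjusted p = 0.00108). That call was lost with an estimated correlation (camera p = 0.317, adjusted p = 0.489), which rests on only 3 arrays and is imprecise. The fry test, which asks whether the list's genes moved one way and compares them with no other genes, missed the threshold (adjusted p = 0.073). The 2 loci taken as markers of endodermis and exodermis also fell, with medians of -2.20, -1.21 and -1.22 on replicates 1, 2 and 3.

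Of the diterpenoid phytoalexin list, whose genes make antimicrobial terpenoids of rice, 7 loci were on the array and 6 were tested. Under vanadate 5 of these rose, 0 fell and 1 was not called, and adjusted over the list alone the same numbers held. As the mean over a gene's probes 4 rose, and with channels as separate samples 3. The strict filter, which leaves out probes dim in water, left 0 called and a median of 0.40. Both other probes of Os04g0178300, 1 of the 5, were not called. The member not called, Os04g0178400, had log2 ratios of -1.68, -0.46 and 1.70 on replicates 1, 2 and 3. Os04g0179700 had a log2 ratio of 4.28 ± 0.60 (SE, adjusted p = 0.00182 in limma). Its water channel was not well above background on any array, so its representative probe has a limit of at least 19.3-fold higher under vanadate. That limit was 9.58-fold without replicate 3 and 32.3-fold without replicate 2. The log2 ratio was 6.58 with the processed signals and 3.12 as the mean over its probes, and the other probe of Os04g0179700 had a log2 ratio of 1.97 ± 0.54 (SE). Os04g0180400 was 6.56-fold higher at 2.71 ± 0.56 (SE, adjusted p = 0.00863 in limma), with water well above background on 2 arrays, and 3.31-fold higher without replicate 3 and 17.8-fold with the processed signals. Os04g0179200 was 4.51-fold higher at 2.17 ± 0.41 (SE, adjusted p = 0.00605 in limma), with water well above background on 1 array, and at least 2.81-fold higher without replicate 3. Its log2 ratio was 3.70 with the processed signals. The list's median was 1.86, above all of 10000 matched random lists, and was larger on replicate 3, at 3.39, than on replicates 1 and 2, at 1.30 and 0.89. It was 2.99 with the processed signals and 2.84 in the authors' value table. The random lists drew each gene independently, while all tested members but Os02g0570400 lie from Os04g0178300 to Os04g0180400 by locus number. Camera estimated a correlation of 0.93 between the members, so independent draws vary too little to judge the median of this list. The camera test missed the threshold (adjusted p = 0.0506), as it did with an estimated correlation (adjusted p = 0.489). The fry test missed it too (adjusted p = 0.318). With slide as a fixed block, where the spread leaves out replicate 3, the camera adjusted p was 0.00072. Over the 14 alternatives that left enough members to test it ranged from 0.00072 to 0.0875. Without replicate 3, that is within the slide of replicates 1 and 2, it was 0.0168 and 1 member was called lower.

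The phosphate starvation list had 4 tested members, with 1 higher, 1 lower and 2 not called, also when adjusted over the list alone. Its words, such as those for phosphate transporters and purple acid phosphatases, matched 0 genes, so most of its intended scope was not covered. Os10g0392600 was lower at a log2 ratio of -0.42 ± 0.08 (SE, adjusted p = 0.00752 in limma). Its vanadate channel was not well above background on any array, and the bound of 1.34-fold lower equalled the fold of its log2 ratio. That bound was 1.28-fold without replicate 2. Its log2 ratio was -1.36 with the processed signals. Os03g0150800 was higher at 0.36 ± 0.12 (SE, adjusted p = 0.0425 in limma), but its 7 other probes were not called. The call of Os10g0392600 was lost without replicate 2 (adjusted p = 0.0656) and under median centring (adjusted p = 0.0619). That of Os03g0150800 was lost without replicate 2 (adjusted p = 0.143), without replicate 3 (adjusted p = 0.134), under median centring (adjusted p = 0.125), in the authors' value table (adjusted p = 0.123) and as the mean over its probes (adjusted p = 0.682). Among 4 tested members of the list of plasma membrane and P-type ATPases, 0 rose, 1 fell and 3 were not called, also when adjusted over the list alone. The words of this list, which included calcium-transporting and phospholipid-transporting ATPases, matched 0 genes. The 4 loci therefore do not stand for P-type ATPases as a whole. The member that fell, Os03g0689300, had a log2 ratio of -0.40 ± 0.11 (SE, adjusted p = 0.0279 in limma), with an adjusted p of 0.0829 without replicate 2, 0.0819 without replicate 3 and 0.0774 as the mean over its probes. The probes of Os04g0656100 in this list disagreed, 1 being called higher, 1 lower and the representative probe not called. Of the probes of Os07g0191200, 1 was called higher, at 0.32 ± 0.09 (SE), and the representative probe was not called.

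The list for the Casparian strip and silicon transport was taken as a marker list of endodermis and exodermis. Its words matched 0 genes, so it held only its 2 loci fixed by ID. Both fell, also when adjusted over the list alone, and under 1 of 16 alternatives only 1 was called lower. Such falls do not tell a change in the share of those cells from a change within them. Os02g0745100 was 4.19-fold lower at a log2 ratio of -2.07 ± 0.20 (SE, adjusted p = 0.000384 in limma). Os03g0107300 was 2.03-fold lower at -1.02 ± 0.20 (SE, adjusted p = 0.0069 in limma). No set test was run on lists with fewer than 5 tested genes.

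**Figure D1:**
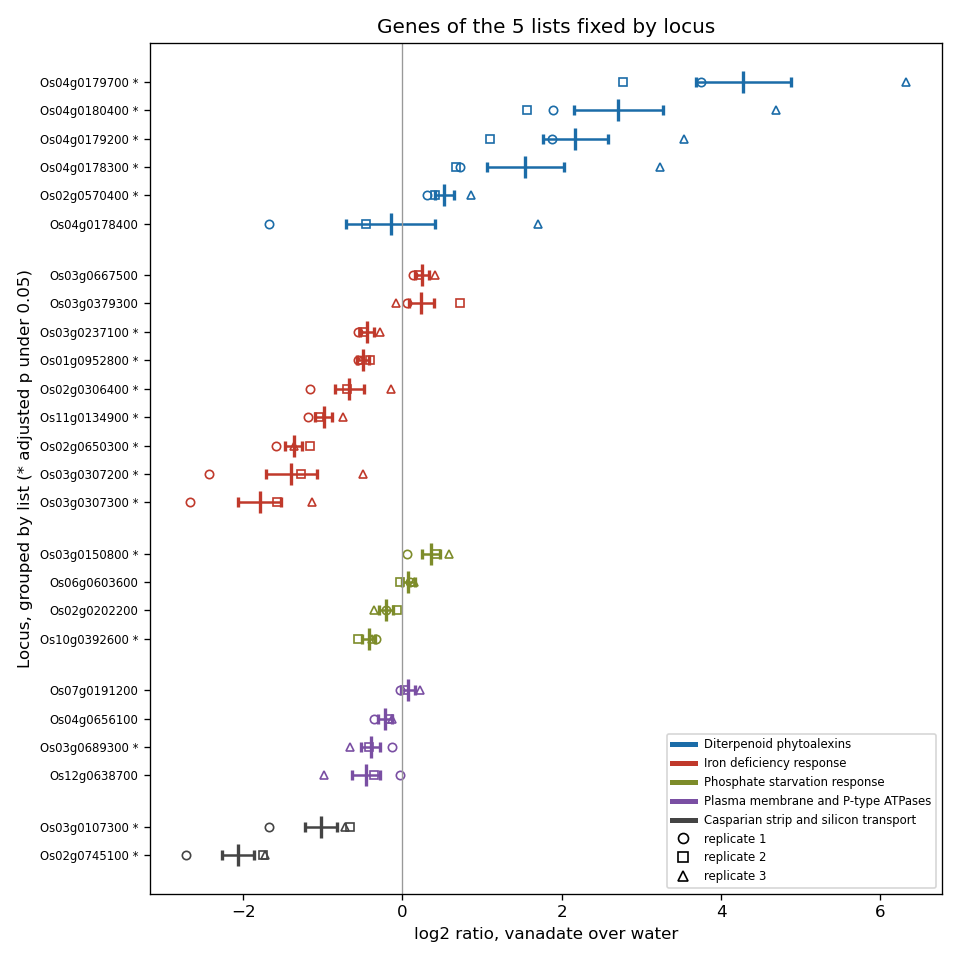
Log2 ratio of vanadate over water (horizontal axis) for each tested gene of the 5 lists fixed by locus (vertical axis), with open symbols for the 3 replicates, a vertical mark for their mean, bars for the moderated SE and an asterisk for an adjusted p under 0.05. Os04g0179700 has the largest mean, 4.28, and Os02g0745100 the smallest, -2.07.

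Of 4 reference genes, 1 fell, 1 rose and 2 were not called. The names given to their locus IDs are background knowledge and were not checked against an annotation. Os03g0718100 (ACT1, actin) was called lower at -0.33 ± 0.09 (SE, adjusted p = 0.0272 in limma), a call lost under median centring (adjusted p = 0.427), with the processed signals (adjusted p = 0.282), as the mean over its probes (adjusted p = 0.101), without replicate 2 (adjusted p = 0.119) and without replicate 3 (adjusted p = 0.0887). Os01g0328400 (UBQ5, ubiquitin) was called higher at 0.38 ± 0.08 (SE, adjusted p = 0.00863 in limma), a call lost under median centring (adjusted p = 0.11) and without replicate 2 (adjusted p = 0.067). Os03g0177900 (EF1a, elongation factor) was at 0.18 ± 0.08 (SE, adjusted p = 0.104 in limma), and was called higher under median centring (adjusted p = 0.0221) and with an intensity trend in the spread (adjusted p = 0.0411). Os04g0486600 (GAPDH, a glycolytic enzyme) was at 0.0011 ± 0.12 (SE, adjusted p = 0.995 in limma), with a sign that turned under 6 of 16 alternatives.

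The array also carried probes for the loci of microRNAs, which are small regulatory RNAs, and 124 of 170 loci were tested. Counted over probes, 41 rose and 44 fell of 183, while 28.4% of all tested probes rose and 20.9% fell. Of the 183, 137 were flanking probes and 46 were named for the mature sequence, of which 6 rose and 7 fell. Flanking probes lie beside the mature sequence by their names, so their values below do not measure the mature microRNA. For 37 loci both the 5' and the 3' flanking probe were tested, and 6 loci rose on both, 13 fell on both and 0 moved in opposite directions. The 2 flanking probes correlated across loci with Pearson's r of 0.857, and loci are not independent replicates. The largest fall on both probes was that of osa-miR171f, with log2 ratios of -1.75 ± 0.09 (SE) and -1.54 ± 0.13 (SE), adjusted p = 2.50e-05 and 0.000198 in limma. osa-miR159a fell by 1.16 ± 0.11 (SE) and by 1.33 ± 0.09 (SE) on the log2 scale, and osa-miR169i fell by 0.93 ± 0.09 (SE) and by 1.05 ± 0.13 (SE). The 3' probe of osa-miR169i was at -2.10 with the processed signals, and the calls of both probes were lost with channels as separate samples (adjusted p = 0.0866 and 0.181). osa-miR399d rose on both probes (adjusted p = 0.00265 and 0.00237 in limma), and as its water channel was not well above background on any array it was at least 1.96-fold and 1.98-fold higher on its probes. Its log2 ratios were 1.06 and 1.16, and 3.68 and 3.27 with the processed signals. Without replicate 2, 3 loci rose on both probes and 6 fell on both, and without replicate 1 the numbers were 4 and 8. They were 4 and 6 under median centring and 2 and 4 with channels as separate samples.

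**Figure D2:**
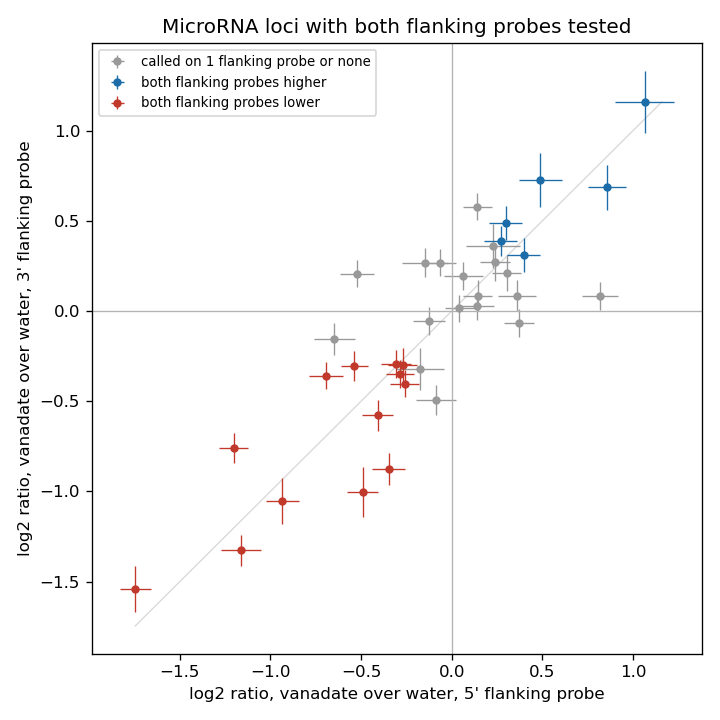
Log2 ratio of vanadate over water on the 5' flanking probe (horizontal axis) and the 3' flanking probe (vertical axis) of 37 microRNA loci, as means of 3 arrays with moderated SE bars and a diagonal line of equal values. The 6 loci called higher on both probes lie in the upper right quadrant and the 13 called lower on both in the lower left.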

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

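The tests of exchanged dyes and of the array of replicate 3 were chosen after the results were seen. Of 59 control probes of the array design that carry no gene name, 52 were well above background in neither channel on any array, and 6 were above background in both channels on all arrays. Of these 6, 4 showed a higher signal in vanadate, in data outside the gene probes, and POsControl0005 at 0.15 ± 0.10 (SE) and POsControl0021 at 0.055 ± 0.028 (SE) were not called. POsControl0004 had a log2 ratio of 1.83 ± 0.06 (SE, n = 3), POsControl0001 of 0.77 ± 0.05, POsControl0027 of 0.19 ± 0.04 and PTaControl0002 of 0.12 ± 0.03. Their limma adjusted p were 4.53e-07, 3.25e-05, 0.0175 and 0.0415, from a fit of the control probes alone. Calls in that fit are not comparable with calls in the gene test. Of the 52 probes above background on no array, 4 were called higher and 4 lower, at -0.16 to 0.18, so the shifts of POsControl0027 and PTaControl0002 are about the size seen without signal.

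More genes rose at least 2-fold than fell at least 2-fold, at a ratio of 5.49. If unsubtracted background in the water channel had made the whole excess, it would have vanished on probes well above background in both channels on all arrays. Yet with the processed signals the ratio there was 2.94 (95% exact binomial interval 2.67 to 3.24), and with the background of negative control spots 4.14. This argues against background as the source of the whole excess, but a partial share stays open. A loess curve forced through the centre is argued against as the source of the whole excess in the same way, with a ratio of 3.81 (95% exact binomial interval 3.44 to 4.23) under median centring. The ratio was 4.19 with the filter alone, 3.66 with the processed signals alone and 5.40 with the background of negative control spots alone. Dye bias cannot be told apart from the treatment, since 0 arrays had exchanged dyes, and a response of the roots to vanadate stays open beside it. The intervals cover counting error only.

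Calls were also counted after exchanging the channels of single arrays. Of the 4 distinct assignments, 1, the one in the labels, gave 11014 called genes, and the highest of the others gave 0. With 4 assignments no share under 0.05 can be reached.

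The phytoalexin list stood higher on the array of replicate 3. Larger log ratios over that whole array are argued against: after removal of the slope of 1.04 between replicate 3 and the mean of replicates 1 and 2, the list's median excess was 2.66, against -0.30 to 0.34 for 95% of random lists matched on replicates 1 and 2. These random lists drew each gene independently, so their range is too narrow for genes that move together. A deviating probe per gene is argued against by the 4 other tested probes of 3 member genes, all with an excess above 0 and a median excess of 1.97 on the log2 scale. The slide, the scan day and the plants of replicate 3 cannot be separated in this design, and a difference among the plants was not tested.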

How the results depend on the processing

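Slide as a fixed block, the negative control background, the processed signals with the strict filter and the counts over single microRNA probes were chosen after the data were seen. Over 17 alternatives, 681 of 790 values kept their direction and side of the threshold or stayed within the spread or 1.5 times, 26 lost a call, 11 gained one, 64 moved and 8 turned. The iron deficiency list kept its direction and its call in camera under all 16 alternatives that tested it. At the preset correlation p ranged from 0.00105 to 0.0424, adjusted over the 2 lists except with the strict filter. That filter left the phytoalexin list too small to test, so p was for 1 list, without adjustment, at 0.0416 under the filter alone. With an estimated correlation that call was lost (adjusted p = 0.489). Processed signals gave 3004 rises and 820 falls of at least 2-fold, and with the strict filter 582 falls. Median centring gave 4217 rises. The authors' value table gave 6872 falls and 1211 falls of at least 2-fold. Its lack of centring shifts every ratio; the cause of the other changes was not tested. The fit with no replicate block, channels as separate samples, gave 3369 rises and 1447 falls and gives up the pairing within arrays.

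At the preset correlation, the camera adjusted p of the phytoalexin list passed the threshold under processed signals (0.0166), median centring (0.00221), the authors' value table (0.0182), no replicate block (0.0341), slide as a fixed block (0.00072) and the negative control background (0.0456), and the cause was not tested. With an estimated correlation the adjusted p was 0.489. At the preset correlation it ranged from 0.00294 to 0.0288 with each replicate left out, and falls ranged from 2761 to 3772. Over the 14 alternatives that tested it, it ranged from 0.00072 to 0.0875. The strict filter, which leaves out probes dim in water, left fewer than 5 members to test, with 0 called and a median of 0.40. That filter left 2 microRNA loci risen and 6 fallen on both probes. Os04g0486600 turned to -0.0049 with no background subtraction, -0.021 in the authors' value table, -0.12 as the mean over probes, -0.035 with slide as a fixed block and -0.00012 with the negative control background, and ranged from -0.16 to 0.090 with each replicate left out, never called. The median of the phosphate list turned from -0.069 to 0.073 under the strict filter, which leaves out Os10g0392600, and to 0.063 with processed signals as well. Slide as a random block was not run, since limma's duplicateCorrelation gave an estimate for 0 of 31108 probes with 3 arrays. Signal over background limits the folds of dim genes, which were larger with the processed signals.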

Other observations

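Genes that rose at least 2-fold lay next to each other along the chromosomes, in the order of their locus numbers. The longest run had 6 adjacent tested genes on chromosome 7, with a median log2 ratio of 1.20, and runs of 5 lay on chromosomes 1, 2 and 5, with medians of 3.00, 2.58 and 1.56. A run of 4 on chromosome 4 ended at Os04g0180400 of the phytoalexin list, with a median of 2.44. Runs were ranked after their values were seen.

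Among 21989 tested genes placed by locus number, 303 adjacent pairs both rose at least 2-fold, against 159 expected from 1000 permutations within chromosomes and 200 in the highest permutation, which argues against chance placement. Hybridisation of 1 transcript to probes of near-identical neighbours may add to the adjacent pairs. Pairs 2 to 5 positions apart numbered 802, against 638 expected and 719 in the highest permutation. The ratio of 1.26 lies between the value set in advance for that explanation and the value set against it, so that explanation stays open. Shared regulation of neighbouring genes is a hypothesis that was not tested.

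Genes whose probe name carries the class COMBINER, a term the files used here do not define, rose at least 2-fold in 13.8% of 1389 tested, against 8.10% of 16027 with the class mRNA and 8.31% of 4572 with the class COMBINER_EST. These differences were not tested.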
